A study of Mus musculus with 10 samples.

How the data were processed

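Bulk RNA sequencing of whole hearts was compared between 5 samples of female mice labelled wild type and 5 labelled as a germline p38δ knockout, all collected 72 h after a 30 mg/kg doxorubicin injection, on a C57BL/6J background per the labels. Per the labels' protocols, hearts were kept in RNA stabilising solution, libraries were made by a sequencing company, and reads were aligned to GRCm39 with STAR 2.5.2. The deposited values are expected counts per gene, and RSEM 1.3.0 is named in the submitters' processing notes. The authors' table held 78298 genes in 10 libraries, and its expected counts were whole numbers, so no rounding was needed. The annotation release, the strand setting and any read trimming are not given in the sources used here. RSEM divides reads that match several genes between them by estimation, so values of near-identical genes are uncertain, as are overlapping and antisense genes. The labels name the samples but do not state a batch, and p-values measure the spread between these samples. Sample titles begin with DOXF in the wild-type-labelled group and with S in the knockout-labelled group. A cohort or batch that went with these titles could not be told from genotype.

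Gene symbols, types and positions came from the GENCODE annotation of GRCm39, in which 78168 of the identifiers were found. Groups were taken from the genotype label of each sample. Library totals ranged from 21403189 to 40627138 counts. Of 20 pairs of libraries within a group, each differed by more than sampling noise, with chi-square per degree of freedom from 9.47 to 179, so none was counted as a duplicate. The totals limit the precision of genes with few counts, and intervals and floors cover counting error only.

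The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the default expression filter with a minimum count of 10, robust dispersion estimates, no covariate, and Benjamini-Hochberg adjustment at 0.05. The filter kept 16700 genes. Standard errors given with edgeR log2 fold changes are approximate: the absolute log2 fold change divided by the square root of its F statistic. CPM values, counts scaled to a common library size, used TMM factors on the totals of tested genes. A gene's exact permutation test used log2(CPM + 1). Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for 39 of 44 lists with at least 5 tested genes. The lists of T and natural killer cells, B and plasma cells, erythroid cells, lung and thymus, and sex-linked genes had too few tested genes and are given only as summed CPM. The same lists were tested with the correlation estimated from each list and with fry. Of 990 list genes, 1 was not found. The main test, alternatives, lists and the rule for named genes were set before the data were examined.

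The rule named the 4 p38 genes, the 10 largest called changes each way among separated genes of mean CPM at least 1 that were not predicted models or pseudogenes, the 5 smallest p, and up to 4 members of each list by p. Genes named outside it are Rab4a, Btbd9, Tpsab1, Polh, Cdkn1a, Scgb1a1, Sftpc, Ucp1, Myh4, Rag1, Dntt, Themis, Paip1, Atp6v0c, Wtap, Zfand3, Abcg1, Gm50240, Gm50244 and Rnps1-ps, all chosen after their values were seen. Some genes that the rule or the tests reached are not reported here.

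Alternatives set in advance were other scalings, DESeq2 1.42.0, limma voom with and without quality weights, 2 other filters, stricter thresholds, 1 surrogate variable from sva 3.50.0, leaving out mitochondrially encoded genes, genes within 20 Mb of Mapk13, and each library in turn. Alternatives chosen after the data were seen left out library 1 labelled wild type together with library 4 labelled knockout, thinned libraries to the smallest total (its bounds were set before its result), added copies to their parents, removed the 20 Mb window from the lists, and repeated the list tests under other scalings, the CPM filter and with libraries or the window left out with an estimated correlation. Copies were sought with BLAST 2.17.0 at 95% identity over at least 200 bases. A sign change was counted as reversed only where the value or its alternative was called, except for Mapk13, where any sign change counted. The procedure was tested on 3 simulated data sets of these 16700 genes with 200 changed genes, where it recovered 25.9% of 1.5-fold, 61.7% of 2-fold and 88.9% of 4-fold changes, and 5.58% of its calls were false. The simulated genes varied independently and no simulated library stood apart, so these rates may not hold for the real libraries.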

Results

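Transcript levels were measured by bulk RNA sequencing in hearts of female mice 72 h after 1 intraperitoneal injection of doxorubicin at 30 mg/kg. Doxorubicin is an anthracycline chemotherapy drug whose use is limited by damage to heart muscle. The comparison was between 5 libraries labelled wild type and 5 labelled as a germline knockout of p38δ, a stress-activated protein kinase encoded by Mapk13. It asks which heart transcripts differ with p38δ genotype after the drug. All 10 hearts had received doxorubicin, so the effect of the drug itself was not measured. Total counts per library ranged from 22082289 to 40627138 in the wild-type-labelled and from 21403189 to 33477767 in the knockout-labelled group.

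Mapk13 (ENSMUSG00000004864, chromosome 17, 28987747 to 28999207, GRCm39) was near the detection limit in 4 of the 5 wild-type-labelled hearts. The wild-type-labelled libraries 1 to 5 held 292, 5, 2, 1 and 4 counts, and the knockout-labelled libraries 1 to 5 held 12, 10, 10, 15 and 9. The fitted log2 fold change in the knockout-labelled group was -1.76 with a standard error of 1.23 (edgeR quasi-likelihood test, adjusted p = 0.78, n = 5 per group). Without library 1 labelled wild type the direction turned, to a log2 fold change of 2.13 that passed the test (adjusted p = 0.0443 by edgeR). That library also held the airway and lung markers described below, so its Mapk13 level could not be assigned to heart muscle. The labels do not say which part of the gene was removed, and the counts do not resolve exons, so transcripts from the remaining exons could not be told from intact ones. The target therefore did not check the labels, and directions below are given between libraries as labelled. The other p38 genes did not pass the test. Mapk14, which encodes p38α, had 56.2 ± 3.60 CPM, the count scaled to library size (SD, n = 5), in the wild-type-labelled and 61.3 ± 4.85 in the knockout-labelled hearts. Mapk12 (p38γ) had 17.5 ± 1.72 and 18.3 ± 2.52 CPM, and Mapk11 (p38β) had 1.94 ± 0.76 and 1.83 ± 0.33 CPM.

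Most of the genes that differed lay on the chromosome that carries Mapk13. Of 16700 genes tested, 59 passed an adjusted p threshold of 0.05, with 40 higher and 19 lower in the knockout-labelled hearts. DESeq2 called 118, 72 higher and 46 lower, with all 59 among them. Of the 59 edgeR calls, 45 were on chromosome 17, or 76.3%, although only 4.95% of the tested genes are located there (two-sided Fisher's exact test over genes taken as independent, p = 3.98e-47). On this chromosome 28 genes were higher and 17 lower, between positions 6307113 and 65745692. Within 20 Mb of Mapk13, 35 of 556 tested genes were called, a share of 6.29%, against 0.0882% of the 15873 genes on other chromosomes. In each of the 59 called genes, all 5 libraries of a group lay above all 5 of the other. Over all tested genes this held for 1.78%, where chance gives 0.794%. Before adjustment, 1145 of the 16700 genes had p under 0.05 by edgeR, where chance gives about 1 in 20. Of the 15873 genes outside chromosome 17, 982 did, which is somewhat above that rate, an excess that was not tested.

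**Figure D1:**
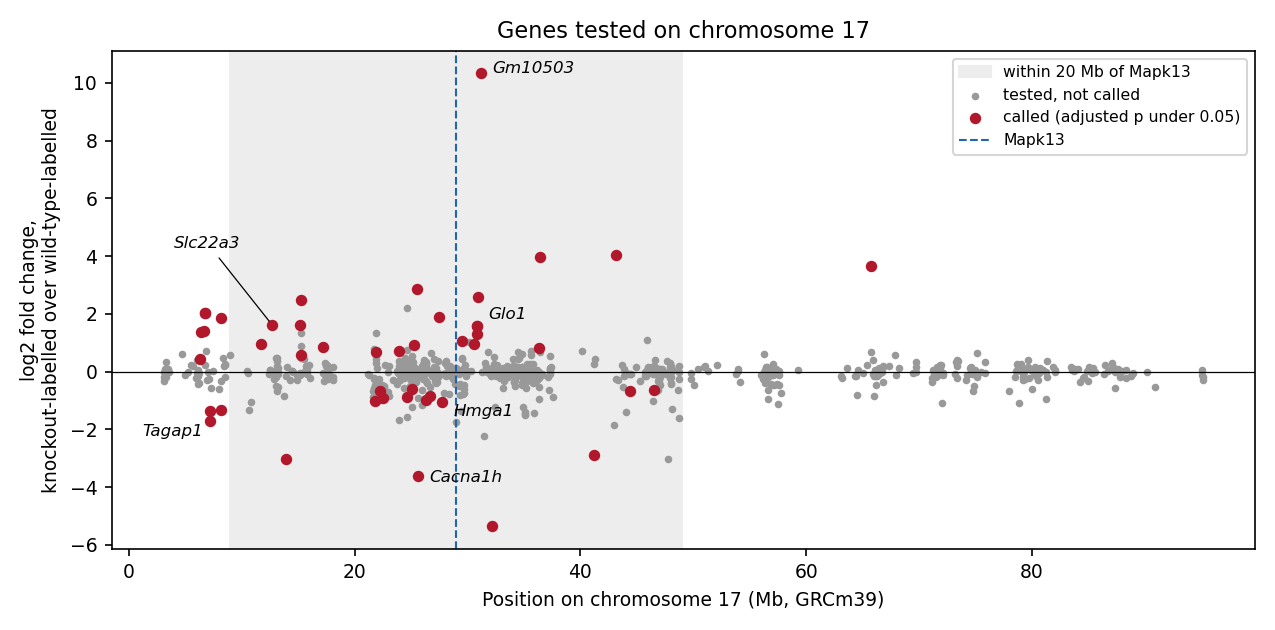
Log2 fold change (knockout-labelled over wild-type-labelled, n = 5 per group) of each gene tested on chromosome 17 against its position in Mb on GRCm39; red points passed the adjusted p threshold and the grey band covers 20 Mb on either side of Mapk13 (dashed line). The 45 called genes lie mainly in and next to the band, 28 above and 17 below 0.

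Glo1 (chromosome 17, 30803910 to 30845845), which encodes the glyoxalase that clears methylglyoxal, rose from 77.8 ± 7.78 to 231 ± 14.0 CPM (SD, n = 5 each; adjusted p = 2.12e-06 by edgeR). It sat in a run of 6 neighbouring called genes, all higher. This run held Btbd9 with a log2 fold change of 0.95, the axonemal dynein gene Dnah8 with 2.58 and the long noncoding RNA Gm10503. Gm10503 stood at 12.4 ± 1.5 CPM in the knockout-labelled hearts and had reads in 1 of 5 wild-type-labelled libraries. Slc22a3 (chromosome 17, 12637847 to 12726614), which encodes organic cation transporter 3, rose from 3.04 ± 1.08 to 9.44 ± 2.78 CPM (log2 fold change 1.63 ± 0.25 SE, adjusted p = 0.0113). It was the called member of the 27 tested genes for doxorubicin handling and topoisomerases. Its call was lost without library 4 labelled wild type (adjusted p = 0.0505) and when libraries were scaled by their totals alone (0.113).

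Among the genes lower in the knockout-labelled hearts, Cacna1h (chromosome 17, 25593259 to 25652764), a T-type calcium channel subunit, fell from 8.08 ± 3.42 to 0.65 ± 0.39 CPM (log2 fold change -3.62, adjusted p = 9.9e-04 by edgeR). The chromatin gene Hmga1 fell from 29.8 ± 4.0 to 14.5 ± 1.89 CPM, and Rnps1, a splicing factor gene, from 54.6 ± 4.45 to 29.4 ± 2.78 CPM. Hmga1 and Rnps1 have near-identical copies elsewhere in the genome, and their sums with those copies were not called (log2 fold changes of -0.05 and 0.20). Decr2, a peroxisomal dienoyl-CoA reductase gene, had a log2 fold change of -0.97, and the zinc finger gene Zfp52 had -1.03. Neurl1b had -0.83 with an adjusted p of 0.0405, a call lost with no filter on low counts (0.234) and when any 1 library other than library 1 labelled wild type was left out. Several called genes were members of closely related families and are uncertain, since reads can be shared between them. Tagap and Tagap1 moved in opposite directions (log2 fold changes of 1.85 and -1.72). Dynlt1a and Dynlt1b were higher (1.37 and 1.40), Rsph3a and Rsph3b lower (-1.33 and -1.35), and Ermardl2 higher (1.60). The Dynlt1a call (adjusted p = 0.0235) was lost when libraries were scaled by their totals alone (0.303) and when any 1 library other than library 1 labelled wild type or library 4 labelled knockout was left out. The Rsph3b call was lost with no filter on low counts (adjusted p = 0.0882).

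Outside chromosome 17, 14 genes were called, 12 higher and 2 lower, and 3 of the 14 were overlapping annotations of 1 locus on chromosome 6. This count was 53 with DESeq2, 25 with voom and quality weights, 23 with no filter on low counts, and 24 without library 1 labelled wild type and library 4 labelled knockout. It was 5 when near-identical copies were summed with their parents on chromosome 17, a step that by construction removed 7 of the 14. Mmrn1 (chromosome 6, 60901960 to 60966362), which encodes the platelet and endothelial protein multimerin 1, fell to 2 counts over the 5 knockout-labelled libraries from 2717 over the 5 wild-type-labelled ones. The ratio of its depth-scaled counts was 0.0869%, with a 95% exact Poisson interval of 0.0105% to 0.314% that covers counting error only. Nnt (chromosome 13, 119470859 to 119566380), the mitochondrial nicotinamide nucleotide transhydrogenase, rose from 49.8 ± 11.6 to 292 ± 27.0 CPM (log2 fold change 2.55 ± 0.17 SE, adjusted p = 6.97e-06 by edgeR). Wdfy1, an adaptor of Toll-like receptor signalling, rose from 10.5 ± 1.03 to 30.2 ± 1.15 CPM (adjusted p = 1.17e-06), and Rab4a, which encodes an endosomal GTPase, from 3.05 ± 0.64 to 7.58 ± 0.99 CPM (adjusted p = 0.00186). Rab4a was named after its values were seen. Nnt and Wdfy1 were the called members of 8 tested genes known to vary between C57BL/6 substrains. In that list Entpd4 had 87.6 ± 16.5 against 61.7 ± 11 CPM and did not pass, and Ide, the insulin-degrading enzyme gene, stood at 165 ± 30.5 against 102 ± 15.5 CPM and did not pass either (adjusted p = 0.0794). It passed without library 1 labelled wild type (0.0387), without library 4 labelled knockout (0.0471), without both (0.00179), with DESeq2 (5.44e-04) and with no filter on low counts (0.00932). The Rab4a call was lost when libraries were scaled by their totals alone (0.0615). The remaining genes included Hmga1b and the pseudogenes Glo1-ps, Atp6v0c-ps2 and Rnps1-ps, with log2 fold changes of 3.40, 3.47, 4.03 and 5.78. These copies can share reads with Hmga1, Glo1, Atp6v0c and Rnps1 on chromosome 17 and are uncertain.

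**Figure D2:**
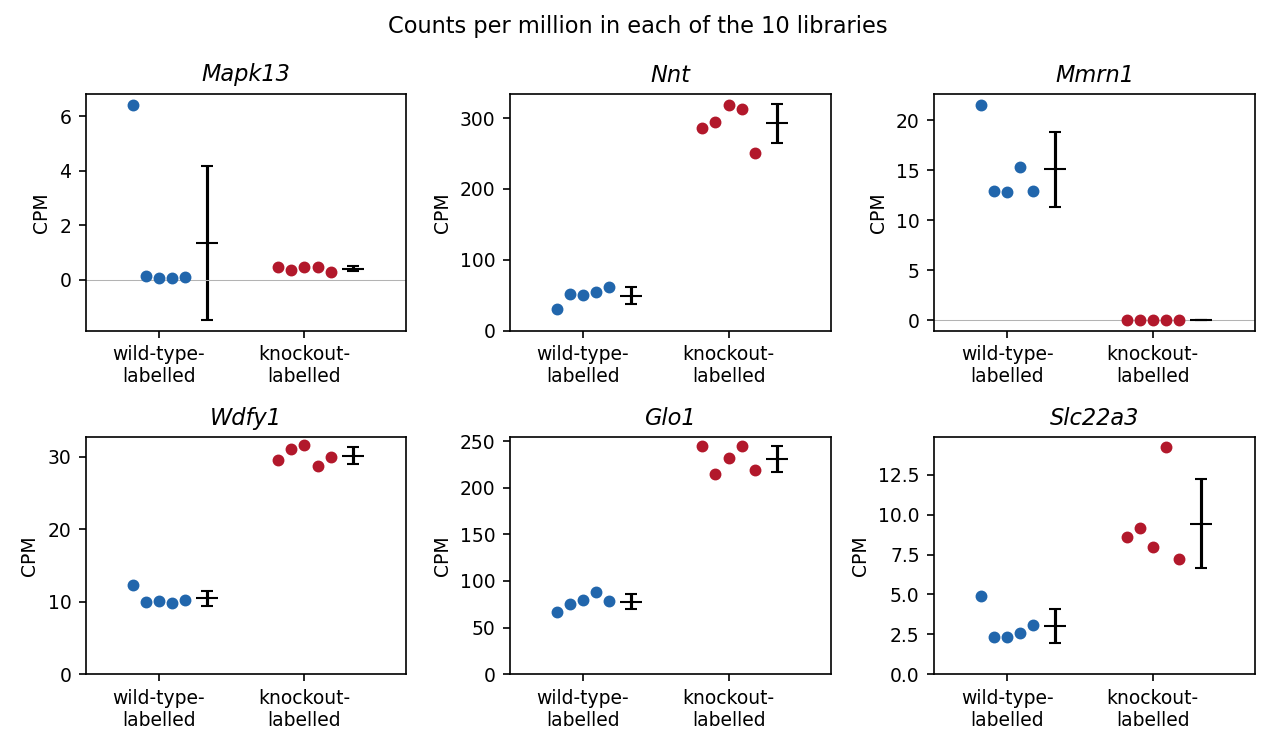
CPM (vertical axes) of 6 genes in each of the 5 wild-type-labelled (blue) and 5 knockout-labelled (red) libraries, with the group mean and SD beside the points. Nnt, Wdfy1, Glo1 and Slc22a3 were higher and Mmrn1 lower in all 5 knockout-labelled libraries, while Mapk13 reached 6.41 CPM in library 1 labelled wild type and at most 0.487 CPM elsewhere.

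Of 39 gene lists tested, 9 were called with the preset correlation (limma camera, Benjamini-Hochberg adjusted), 7 lower and 2 higher in the knockout-labelled hearts. With the correlation estimated from each list, camera called 0 lists and none had an unadjusted p under 0.05; every list had an adjusted p of 0.859 or more with an estimated correlation. Nor was any list called with an estimated correlation when 1 library was left out at a time (lowest adjusted p = 0.694, with at most 1 unadjusted p under 0.05). The self-contained fry test called only the substrain list (adjusted p = 0.0013) and gave 3 unadjusted p under 0.05. Of 100 splits of the 10 libraries into 5 and 5, the real one included, 94 called at least 9 lists. The interferon response list was lower, with a median log2 fold change of -0.39 over 46 genes and 41 of them below 0 (adjusted p = 2.58e-11, and 0.859 with an estimated correlation). None of its members passed over all genes tested, and 1 was lower when adjusted over the list alone. Its members with the smallest p included the nucleotide kinase gene Cmpk2 (9.45 ± 1.35 against 6.47 ± 0.87 CPM), the antiviral gene Ifit3 (41.2 ± 27.7 against 17.1 ± 5.29 CPM) and the guanylate-binding protein gene Gbp2 (26.3 ± 10.7 against 15.5 ± 2.07 CPM). The wild-type SDs of Ifit3 and Gbp2 came largely from library 1, at 90.0 and 45.3 CPM. Without that library the list was still lower (median -0.17, adjusted p = 1.76e-07, and 0.894 with an estimated correlation).

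Markers of mesothelium and epicardium, the outer lining of the heart, were lower as a list, with a median log2 fold change of -1.17 and all 12 genes below 0 (adjusted p = 1.24e-08, and 0.859 with an estimated correlation). None passed over all genes tested, and 11 were lower when adjusted over the list alone. The uroplakin gene Upk3b had 11.1 ± 7.51 against 3.65 ± 1.76 CPM, the keratin gene Krt19 4.98 ± 6.88 against 1.03 ± 0.47 CPM, and Gpm6a 15.5 ± 9.43 against 6.94 ± 2.51 CPM. Their log2 fold changes moved from -1.605, -2.261 and -1.162 to -1.077, -0.862 and -0.7039 when library 1 labelled wild type was left out. With library 4 labelled knockout left out too, Upk3b passed over all genes (adjusted p = 0.00458 by edgeR). Krt19 and Gpm6a did not (0.132 and 0.276). Without library 1 labelled wild type the list median was -0.64 (adjusted p = 1.55e-07, and 0.894 with an estimated correlation). Atrial cardiomyocyte markers were lower too, with all 10 tested genes below 0 and a median of -0.99 (adjusted p = 8.48e-04, and 0.859 with an estimated correlation). 3 passed when adjusted over the list alone and none over all genes. The atrial light chain genes Myl7 and Myl4 and the secreted factor gene Dkk3 led this list, and Myl7 stood at 40.2 ± 75.1 against 0.21 ± 0.12 CPM. Without library 1 labelled wild type the atrial median was -0.28 (adjusted p = 0.0167, and 0.894 with an estimated correlation). Library 2 labelled wild type then had the highest levels, with Myl7 at 25.2 CPM and summed markers of 501 CPM. The sums were 215 to 226 CPM in libraries 3 to 5 labelled wild type and 204 to 281 CPM in the knockout-labelled ones. Macrophage and monocyte markers, among them the scavenger receptor gene Cd163 (46.1 ± 26.4 against 25.8 ± 7.58 CPM) and Lyve1, had a median of -0.59 (adjusted p = 0.0225, and 0.859 with an estimated correlation). That call ended without library 1 labelled wild type (median 0.01, adjusted p = 0.963), and also without library 1 or library 4 labelled knockout (0.0712 and 0.0626) and when libraries were scaled by their totals alone (0.201).

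Targets of p53, the transcription factor induced by DNA damage, were lower as a list, with 25 of 30 genes below 0 and a median of -0.23 (adjusted p = 0.00148, and 0.859 with an estimated correlation). No member passed alone. Examples were Sesn2, a stress-induced regulator of growth signalling (5.36 ± 1.39 against 3.96 ± 0.48 CPM), and the RNA-binding protein gene Zmat3 (14.3 ± 2.68 against 11.5 ± 1.13 CPM). At the preset correlation the call held without library 1 labelled wild type (median -0.14, adjusted p = 0.00968, and 0.894 with an estimated correlation). It was lost when library 4 labelled knockout was left out with it (adjusted p = 0.0637). In that knockout-labelled library the p53 target Cdkn1a, a cell cycle inhibitor, stood at 13.7 CPM, against 65.9 to 105 CPM in the other 9, a gene chosen after its values were seen. The endoplasmic reticulum stress and integrated stress response list (median -0.11) and the cell cycle list (median -0.16) each had an adjusted p of 0.0378, and 0.859 with an estimated correlation. Dnajb9, an endoplasmic reticulum chaperone gene, had 65.8 ± 5.11 against 58.8 ± 3.13 CPM, and the proliferation marker Mki67 had 2.15 ± 1.27 against 1.08 ± 0.31 CPM. Neither list was called without library 1 labelled wild type (medians -0.0417 and 0.00224, adjusted p = 0.198 and 0.963). Nor was either called when libraries were scaled by their totals alone (0.0562 and 0.161). The cell cycle list was also not called with a CPM of at least 1 in 5 libraries (0.109). Leaving out other single libraries also ended the calls of both lists, up to 0.201 for the stress list without library 4 labelled knockout.

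Fatty acid oxidation genes were higher as a list, with 31 of 32 genes above 0 and a median of 0.12 (adjusted p = 0.00483, and 0.859 with an estimated correlation). Eci1, a mitochondrial enoyl-CoA isomerase gene on chromosome 17, had 126 ± 21.9 against 210 ± 43.8 CPM and was the 1 member higher when adjusted over the list alone. The 15 mitochondrially encoded genes had a median of 0.14 (adjusted p = 0.0127, and 0.859 with an estimated correlation), with mt-Nd1 at 22070 ± 4691 against 27480 ± 3878 CPM and mt-Nd5 at 28790 ± 6057 against 33880 ± 1491 CPM. Cpt1a, the carnitine palmitoyltransferase gene at the entry of fatty acids into mitochondria, had 84.2 ± 16.3 against 103.9 ± 9.41 CPM. Neither list was called without library 1 labelled wild type (medians 0.0139 and 0.0228, adjusted p = 0.981 and 0.781), which had the lowest share of mitochondrially encoded counts. Without library 1 labelled knockout the adjusted p values were 0.0507 and 0.0606, and fatty acid oxidation also missed the threshold without library 5 labelled knockout (0.0519).

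**Figure D3:**
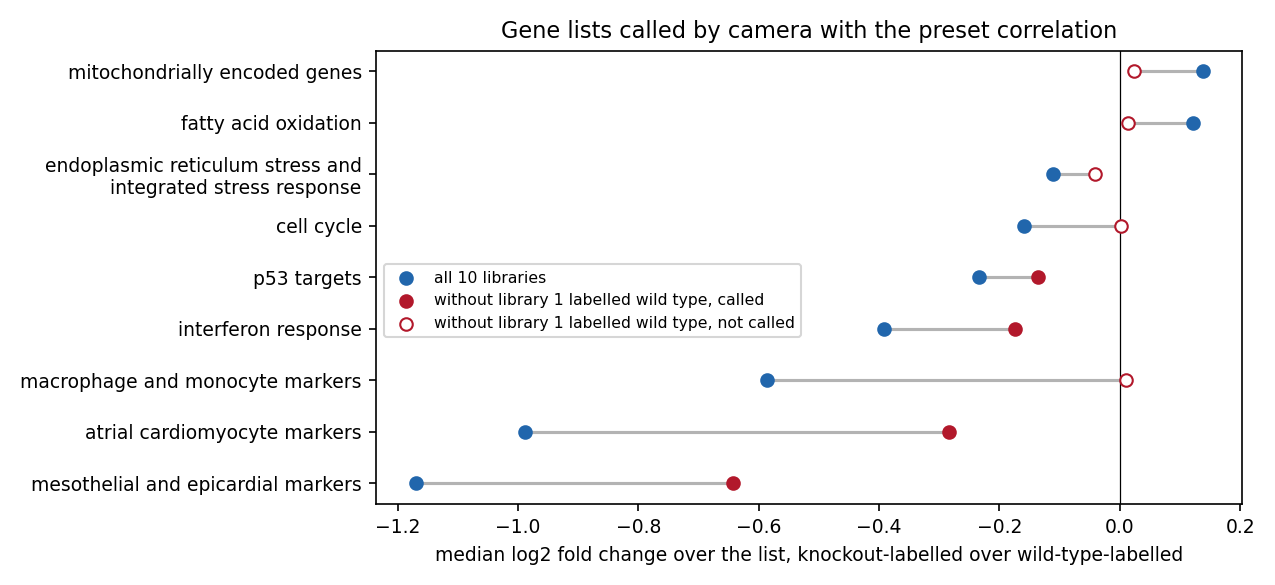
Median log2 fold change (knockout-labelled over wild-type-labelled) of the 9 called gene lists with all 10 libraries (blue) and without library 1 labelled wild type (red, filled where the list was still called). The mesothelial median moved from -1.17 to -0.64 and the macrophage median from -0.59 to 0.01.

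The p38 MAPK pathway list did not pass (28 genes, 13 above and 15 below 0, adjusted p = 0.322), and its median was just below 0 while its mean and its test pointed up. Its members included Tab2, an adaptor of the kinase TAK1 (68.8 ± 2.79 against 76.1 ± 1.06 CPM), and the transcription factor gene Mef2c (67.2 ± 2.05 against 74.8 ± 7.76 CPM). Doxorubicin handling and topoisomerase genes did not pass as a list (median -0.10, adjusted p = 0.149), and the drug efflux pump gene Abcb1b stood at 19.98 ± 4.47 against 14.4 ± 2.46 CPM. That list passed, lower, when genes within 20 Mb of Mapk13 were left out (adjusted p = 0.0355, and 0.78 with an estimated correlation). Cardiac stress and fetal genes did not pass either (median -0.10, adjusted p = 0.884), with the stress-induced gene Ankrd1 at 755 ± 148 against 550 ± 97.1 CPM and the nicotinamide riboside kinase gene Nmrk2 at 10.4 ± 2.96 against 15.9 ± 3.51 CPM. Smooth muscle and pericyte markers had a median of 0.26 (adjusted p = 0.0613), with Notch3, Pdgfrb and Cspg4 at log2 fold changes of 0.26, 0.33 and 0.34. The mean of this list, -0.0954, had the opposite sign. The list passed without library 1 labelled wild type (adjusted p = 0.0135, and 0.894 with an estimated correlation) and without library 5 labelled knockout (0.0256, and 0.767 with an estimated correlation). It also passed when libraries were scaled by their totals alone (0.0068), with a CPM of at least 1 in 5 libraries (0.0374) and without library 1 labelled wild type and library 4 labelled knockout together (0.0274). These had adjusted p values of 0.956, 0.837 and 0.945 with an estimated correlation. Antigen presentation genes went both ways, with H2-Q7 at 0.73 and H2-M3 at -0.89, and 17 of the 21 members lie within 20 Mb of Mapk13 (adjusted p = 0.688). That list passed, higher, without library 1 labelled wild type (adjusted p = 0.00818, and 0.959 with an estimated correlation), and its median of -0.01 and mean of 0.08 differed in sign.

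The other lists did not pass with all 10 libraries. Oxidative phosphorylation genes had an adjusted p of 0.10 with 36 of 47 above 0, while the complex I gene Ndufb10 stood at 203 ± 48.3 against 169 ± 27.9 CPM. This list was called in opposite directions. It was lower without library 1 labelled wild type (median -0.0773, adjusted p = 0.00436) and higher without library 4 labelled wild type (median 0.14, adjusted p = 6.95e-05). It was also higher without library 3 (0.0306) or 5 (0.047) labelled wild type and without library 2 (0.00598) or 5 (0.0195) labelled knockout. The adjusted p values of these calls were 0.716 to 0.959 with an estimated correlation. The tricarboxylic acid cycle list was likewise lower without library 1 (0.0375, and 0.959 with an estimated correlation) and higher without library 4 labelled wild type (0.0348, and 0.719 with an estimated correlation). Sarcomere genes, with an adjusted p of 0.10 and the filamin gene Flnc at 139 ± 10.4 against 155 ± 20.8 CPM, were higher without library 4 (0.00109) or 5 (0.0244) labelled wild type or library 2 labelled knockout (0.0122). Without library 1 labelled wild type and library 4 labelled knockout together, the oxidative phosphorylation (1.58e-06), tricarboxylic acid cycle (7.47e-05), sarcomere (0.0011), glycolysis (0.0457) and cardiomyocyte (0.00219) lists were lower. Each of these had an adjusted p of 0.945 with an estimated correlation. Glycolysis and cardiomyocyte markers were higher without library 4 labelled wild type (0.0449 and 0.0269), and these and the sarcomere calls had adjusted p values of 0.716 to 0.745 with an estimated correlation. Glycolysis (0.39 with all libraries) included the hexokinase gene Hk1 at 116 ± 12.8 against 134 ± 16.1 CPM. Endothelial markers (0.249) went both ways, with the growth factor receptor gene Kdr at 92.6 ± 14.4 against 129.6 ± 29.1 CPM and the von Willebrand factor gene Vwf at 68.8 ± 17.5 against 49.7 ± 5.64 CPM. Fibroblast markers (0.0808) and extracellular matrix and fibrosis genes (0.494) shared the decorin gene Dcn, at 773 ± 244 against 558 ± 33.5 CPM. Skeletal muscle markers (0.575) had a median of -3.69, set by genes such as the fast troponin gene Tnnt3 at 23.8 ± 52.6 against 0.89 ± 0.76 CPM. Without library 1 labelled wild type that median was 0.85 and the list passed, higher (adjusted p = 0.00504, and 0.894 with an estimated correlation). Without library 4 labelled knockout as well, the median was 0.0734 and the list did not pass (0.262). With all 10 libraries the adjusted p values were 0.249 for cardiomyocyte, 0.132 for neutrophil, 0.318 for adipocyte and 0.181 for Schwann cell and neuron markers. They were 0.0613 for cytokines, chemokines and acute inflammation, 0.0808 for cell death machinery and for immediate early genes, 0.132 for calcium handling and conduction and 0.141 for circadian clock genes. They were 0.322 for autophagy and lysosome, 0.354 for the tricarboxylic acid cycle, 0.361 for the glucocorticoid and fasting response, 0.481 for ribosomal proteins and 0.575 for iron handling and ferroptosis. They were 0.853 for antioxidant genes, 0.859 for hypoxia and 0.884 for heat shock proteins. The substrain list had 0.249 by camera. Leaving out library 4 or 5 labelled wild type or library 1 or 2 labelled knockout, among others, brought calls at adjusted p values of 5.62e-05 to 0.0467. These were of the calcium handling, cytokine, cell death, immediate early, fibroblast, neutrophil and ribosomal protein lists, and none held with an estimated correlation (adjusted p of 0.694 or more). The cytokine list was also called with RLE factors (0.0457, and 0.82 with an estimated correlation). With genes within 20 Mb of Mapk13 left out, the cytokine (0.0413) and fibroblast (0.0206) lists were called, each at 0.78 with an estimated correlation. The antigen presentation (0.0457) and immediate early (0.0413) lists were called without library 1 labelled wild type and library 4 labelled knockout together, each at 0.945 with an estimated correlation. The median of the antioxidant list lay above 0 with its mean and test below, and the median and mean of the hypoxia list lay below 0 with its test above.

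Libraries differed within groups in markers of other tissues. Library 1 labelled wild type had 33302 counts of Scgb1a1, the airway secretory protein gene, and 933 of Sftpc, a surfactant gene of lung alveoli. Library 3 labelled wild type had 2199 counts of Scgb1a1, and no other library had more than 21. Summed atrial markers in library 1 labelled wild type were 1670 CPM, and the highest other library had 501 CPM. Its summed cardiomyocyte markers were the lowest of the 10 libraries, at 25000 CPM, and library 4 labelled knockout had the highest, at 70700 CPM. Library 2 labelled knockout had the highest summed T and natural killer cell markers, at 34.9 CPM, against 1.38 to 11.2 CPM in the others. These differences accompany the mesothelial, atrial, macrophage and interferon lists above. For mesothelial markers the groups also differed apart from library 1. Their sums were 367 to 460 CPM in libraries 2 to 5 labelled wild type and 206 to 343 CPM in the knockout-labelled libraries.

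**Figure D4:**
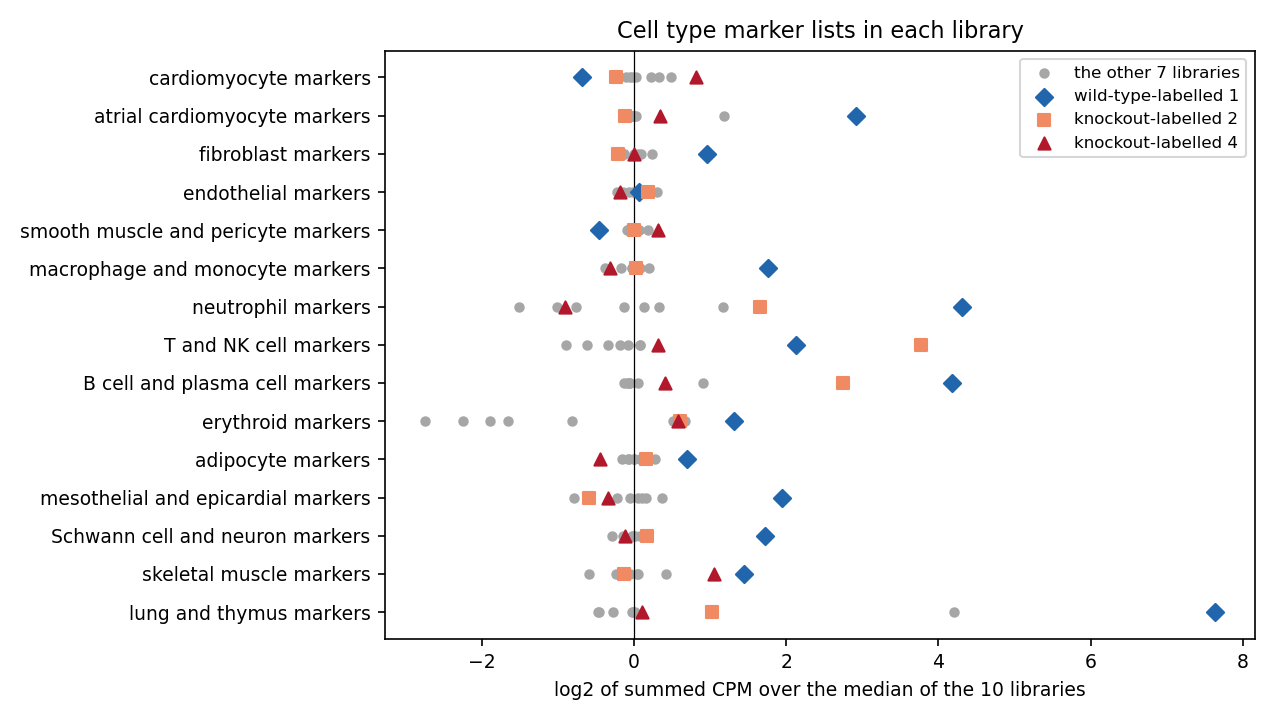
Summed CPM of each cell type marker list in each of the 10 libraries, as log2 of the value over the median of the 10 (horizontal axis). Library 1 labelled wild type (diamonds) is highest for 11 of the 15 lists, and library 2 labelled knockout (squares) for T and natural killer cell markers.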

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

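All tests weighed in this part were chosen after the results were seen. In groups of 5 libraries, 68 of the 260 examined had 1 library whose gap to its nearest neighbour exceeded 0.71 of the group's range, where chance gives about 1 in 20, or 13. Of these, 50 concerned library 1 labelled wild type, 8 library 4 and 6 library 2 labelled knockout, and 4 other libraries. Values from 1 library are not independent of each other. Some of the genes examined were chosen after their values were seen, and the chance rate assumes normally distributed values. The 13 is therefore no fair expectation for this set, and the excess of 68 over it is not a test.

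In library 1 labelled wild type the ratio of gap to range for single genes was, by gene, Abcg1 0.874, Cacna1h 0.777, Cd163 0.763, Dcn 0.797, Dkk3 0.854, Dnah8 0.771, Dynlt1a 0.745, Gbp2 0.895, Gm10503 1, Gpm6a 0.795, Ifit3 0.839, Krt19 0.96, Lyve1 0.855, Mapk13 0.987, Mki67 0.739, mt-Nd1 0.746, mt-Nd5 0.755, Myl4 0.834, Myl7 0.857, Paip1 0.745, Scgb1a1 0.907, Sftpc 0.999, Tnnt3 1, Upk3b 0.875 and Wdfy1 0.802. The Gm10503 ratio lies at the detection floor, from 0.022 CPM in this library and 0 in the other wild-type-labelled ones. For the library as a whole the ratio was, by measure, the share of mitochondrially encoded counts 0.758, the first principal component 0.78, the TMM factor 0.828 and the share of counts in the 20 highest genes 0.736. For summed lists the ratio was, by list, adipocyte markers 0.919, antigen presentation 0.733, atrial cardiomyocyte markers 0.803, B cell and plasma cell markers 0.944, cell cycle 0.784, cytokines, chemokines and acute inflammation 0.774, erythroid markers 0.844, extracellular matrix and fibrosis 0.728, fatty acid oxidation 0.752, fibroblast markers 0.803, heat shock proteins 0.843, interferon response 0.745, lung and thymus markers 0.911, macrophage and monocyte markers 0.856, mesothelial and epicardial markers 0.907, mitochondrially encoded genes 0.776, neutrophil markers 0.909, p38 MAPK pathway 0.73, Schwann cell and neuron markers 0.961, skeletal muscle markers 0.741 and T and NK cell markers 0.892.

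In library 4 labelled knockout the ratio for single genes was Dynlt1b 0.724, Rsph3b 0.76, Scgb1a1 0.742 and Slc22a3 0.722, and for summed lists atrial cardiomyocyte markers 0.766, cell cycle 0.797, doxorubicin handling and topoisomerases 0.808 and skeletal muscle markers 0.738. The Scgb1a1 ratio rests on 21 counts in library 4 and at most 5 in the other knockout-labelled libraries. In library 2 labelled knockout the ratio was Rag1 0.969 for a single gene, and for summed lists antigen presentation 0.795, B cell and plasma cell markers 0.936, lung and thymus markers 0.725, neutrophil markers 0.801 and T and NK cell markers 0.946. The other 4 ratios were 0.827 for Vwf in library 1 labelled knockout, 0.845 for Cpt1a in library 3 labelled knockout, 0.886 for erythroid markers in library 5 labelled knockout and 0.756 for Cpt1a in library 4 labelled wild type.

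Library 1 labelled wild type stood apart from the other 9, with correlations to them of 0.93 to 0.953 where the others had 0.969 to 0.987 among themselves, and depth did not set it apart, since its total ranked 3 of the 10. A wrong genotype label was left undecided by a first count, in which this library lay nearer the knockout-labelled mean in 12 of 75 genes called from the other 9 libraries, between the bounds set of under 10% and over 50%. A second test, added with that count known, argued against it: this share was 16%, where the knockout-labelled libraries, each left out in turn, gave 89.3% to 100% and the other wild-type-labelled ones 0% to 5.88%, and Nnt and Glo1 stood at 30.4 and 66.6 CPM in this library against at least 250 and 215 CPM in them. Tissue from outside the heart muscle was left undecided by 5 of 11 tested cell type lists highest here at over 2 times the next, but a narrower test, added once that was known, found 7 of the 10 detected lung and thymus list members highest at over 2 times the next, among them Scgb1a1 at 732 CPM and Sftpc at 20.5 CPM, and not Dntt, Themis and Rag1. Lung or airway tissue in the sample is therefore a candidate source of part of the pattern, and other tissue stays open too. The brown fat gene Ucp1 had 2068 counts here and at most 5 in any other library. The fast skeletal muscle myosin gene Myh4 had 782 counts here and at most 140 in any other. Both genes were chosen after their values were seen. Summed adipocyte and skeletal muscle markers were highest here at only 1.34 and 1.31 times the next. Among cell type lists too small to test, lung and thymus (10.8 times the next) and B and plasma cell markers (2.69 times) were highest here. Erythroid markers were highest here at 1.56 times, and T and natural killer cell markers were highest in library 2 labelled knockout. An exchange with a wild-type heart from outside the series stays open. No biological explanation was tested because the design gives none within a group.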

How the results depend on the processing

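No paired analysis was possible because the labels give the wild-type and knockout samples no shared replicate numbers. Alternatives chosen after the data were seen left out library 1 labelled wild type and library 4 labelled knockout together, thinned the libraries (with bounds set before the result), summed copies with their parents, took the 20 Mb window out of the lists, and repeated these and the single-library, scaling and CPM filter list tests with an estimated correlation. DESeq2 called 118 genes, 72 higher and 46 lower, with 53 outside chromosome 17, and 59 of the 59 calls were shared. Voom with quality weights called 33 lower and 25 outside chromosome 17, and no filter on low counts gave 23 outside. Leaving out the 20 Mb window left 24 genes by construction, 19 higher and 5 lower, with 10 on chromosome 17. Without both doubted libraries 32 were lower and 24 lay outside chromosome 17, with 57 calls shared. With copies summed 5 lay outside, since 7 called copies were by construction no longer counted as separate genes. A minimum absolute log2 fold change of 1 left 11 lower and 28 on chromosome 17. The other alternatives gave totals within 1.5 times of the main count. Leaving out 1 library at a time gave totals from 47 to 75, from 32 to 50 higher, from 15 to 25 lower, from 36 to 56 on chromosome 17 and from 11 to 19 outside. Scaling by totals alone moved the median of all genes to -0.116.

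Mapk13 turned to 0.65 with voom, and leaving out 1 library gave -2.06 to 2.13. It had no value with a CPM minimum of 1 in 5 libraries or without both doubted libraries, since it failed those filters, and its DESeq2 adjusted p was not given. The sum of Rnps1 with its copies had a log2 fold change of 0.20. Over the alternatives, the 183 other named genes stayed on their side of the threshold in 3403 values, 54 of which, in 30 uncalled genes, changed sign. They lost a call in 29 values of 8 genes, gained one in 19 values of 10 genes, and a called gene changed sign in 1, the sum of Rnps1. Tpsab1, Polh, Rab4a, Slc22a3, Dynlt1a, Neurl1b, Rsph3b and Hmga1 were the genes that lost a call.

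List counts were 0 with an estimated correlation, with all libraries and in each such repeat, and 1 with fry. With the preset correlation they ranged from 6 to 19 without 1 library, with 19 without library 4 and 16 without library 5 labelled wild type, 14 without library 2 and 6 without library 1 labelled knockout. Lists stayed on their side in 1077 values, and in 112 of these, in 20 lists, the direction of the test turned with no call on either side. They lost a call in 184, gained one in 45 and, where the list was called with all libraries or under the alternative, turned in 14 values of 8 lists. Without both doubted libraries the medians were -0.14 for oxidative phosphorylation and for the tricarboxylic acid cycle, -0.12 for glycolysis, -0.15 for sarcomere, -0.19 for cardiomyocyte and 0.0236 for macrophage markers. Without 1 library they ranged from -0.0773 to 0.14 for oxidative phosphorylation, -0.0772 to 0.11 for the tricarboxylic acid cycle, 0.0139 to 0.16 for fatty acid oxidation, -0.75 to 0.0109 for macrophage and -4.09 to 0.85 for skeletal muscle markers. Except where an alternative itself removed genes, libraries or copies, the cause was not tested. With simulated counts of these library sizes and dispersions, changes of 1.5-fold were recovered in 25.9% of genes.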

Other observations

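In this part the tests on copies, strain background and the genes around Glo1, and the choice of Paip1, Tpsab1 and Polh, came after the results were seen. The thinning was an alternative added after the data were seen, with its bounds set before its own result, and the edgeR test and its single-library, filter and scaling alternatives were set in advance. Paip1, the gene of a translation factor partner, stood at 55.3 ± 7.44 against 42.7 ± 3.10 CPM and lies on chromosome 13 like Nnt. It passed without library 1 labelled wild type (adjusted p = 0.00677 by edgeR), and not with all 10 libraries (0.38). Tpsab1, a mast cell tryptase gene on chromosome 17, rose from 0.123 ± 0.0882 to 0.996 ± 0.207 CPM (adjusted p = 0.0113), and Polh, a DNA repair polymerase gene on the same chromosome, fell from 6.54 ± 0.228 to 4.19 ± 0.389 CPM (0.0122). The Tpsab1 call was lost without library 2 or 3 labelled wild type (0.0572 and 0.0586), and the Polh call without library 3 (0.0586), with no filter on low counts (0.10) and when libraries were scaled by their totals alone (0.0615).

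The 59 calls were not matched by chance splits: 1 of 100 splits drawn from the 126 gave as many, the real one, and the highest other gave 2. Depth did not account for them, since 55 genes were called after thinning to the smallest total. Variants carried along with the targeted locus may account for much of the pattern, as 59.3% of the calls lay within 20 Mb of Mapk13, over the bound of more than 50% set before the result was seen. Loss of p38δ itself stays open for each gene and was not tested, since no second line was measured. A cohort or batch that differed between the groups, whose sample titles differ in form, could not be tested either.

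The 14 calls outside chromosome 17 may come in part from reads shared with near-identical copies near Mapk13 and in part from the background strain. The first test written for shared reads left the question undecided: 7 of the 14 genes, or 50%, had such a copy, where over 50% was set to speak for it and under 10% against it. Since 3 of the 7 were overlapping annotations of 1 chromosome 6 locus, the count by locus was 5 of 12, or 41.7%, against 14 of 494, or 2.83%, for random genes (one-sided Fisher's exact test, p = 2.88e-05). The random genes were not matched for gene type, and several called genes with a copy were pseudogenes. This comparison therefore cannot tell gene type from nearness to Mapk13. The first test was then followed, with the outcome and the sums already known, by another: the sums of parents and copies had a median absolute log2 fold change of 0.05, and 1 of 5 sums, that of Glo1, was called, so the second result weighs little on its own. For the strain, 2 of 8 tested genes of the substrain list, Nnt and Wdfy1, were called (one-sided Fisher's exact test, p = 5.9e-05), and a candidate explanation is a substrain that lacks Mmrn1 and carries intact Nnt in the ancestry of the knockout-labelled mice.

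The count of 9 called gene lists cannot be set apart from chance splits: 94 of 100 splits gave as many lists, with a median of 15 and a highest other of 24. No single list was followed across the splits, so the count does not judge any list on its own. Splits that call more lists than the real one point to a structure of the samples, and each split places library 1 labelled wild type, which stood apart, in 1 of its groups.

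The run of 6 called genes from Btbd9 to Gm10503 (chromosome 17, 30434498 to 31182301) was flanked by Zfand3 at a log2 fold change of 0.03 and Abcg1 at 0.00. These annotations are not independent, since Gm50240 overlaps Btbd9, and Gm50244 and Dnah8 overlap Glo1, so shared reads can lengthen the run. The folds of the protein-coding genes were unequal, at 1.94 for Btbd9, 2.98 for Glo1 and 5.99 for Dnah8. A single copy-number step shared by whole genes would leave their ratios alike in both groups, and as the only cause it was argued against by 4 of the 10 ratios among the 5 members with reads in every library, that of Btbd9 to Glo1 included (exact two-sided permutation test, p = 0.00794, the smallest possible, and 0.0397 adjusted over the 10). Extra copies of parts of the segment, or copies together with another cause, could still raise these genes, and RNA counts cannot separate this from regulatory variants, so it stays open.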
